A study of Homo sapiens with 6 samples.

How the data were processed

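Messenger RNA libraries from 6 HEK293 samples, 3 wild type and 3 STAT5B knockout, were compared. The kit named in the labels is an mRNA library kit, and whether it keeps strand is not given in the sources used here. Groups were taken from the genotype label, and some sample names use a word for the control that the labels do not explain. FastQC, fastp, DRAGEN and Picard and the genome build hg38 are named per the submitters' processing notes, with no versions or roles. The annotation release behind the counts and the way reads were assigned to genes are not given in the sources used here.

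Each deposited file held 1 row per gene with its length, effective length, TPM (transcript abundance scaled to 1000000) and estimated count, per the file headers. The deposited estimated counts need not be whole, and 7.12% to 7.64% of values were not. They were rounded to whole numbers before any count test. The TPM values deposited by the authors summed to 1000000 in each library and were used for 1 alternative only. The deposited lengths and effective lengths, in bases, were used for offsets and for the length trend.

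Of 60609 gene identifiers per file, 60340 (99.56%) matched a name table after the version was removed and 42005 had a symbol. Positions came from GENCODE release 29 for 58502 identifiers, on the same genome build. The 45 Y copies of pseudoautosomal genes held a count of 0.

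Total estimated counts were 17686407, 19040818 and 20279181 in the wild type and 17613140, 21099813 and 17494958 in the knockout. The 10 most abundant genes took 3.32% to 3.58% of a library. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom of 2.41 to 7.52 over genes with at least 20 counts in a pair, so no library was counted as a copy of another. TMM scaling factors and dispersions were estimated by edgeR, and the biological coefficient of variation was 4.43%.

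The comparison used edgeR 4.0.16 in R 4.3.3 with filterByExpr (minimum count 10, minimum total 15), TMM scaling and the quasi-likelihood F test of group, with Benjamini-Hochberg adjustment over 15958 genes and a threshold of 0.05. Another 44651 genes were not tested because of low counts. Fold changes are knockout against wild type. CPM are counts scaled to 1000000 on the TMM-scaled library sizes, with the SD over 3 libraries. For a gene with 0 counts in a group the fold is a bound against 3 counts over the group, and for 1 to 3 counts a ratio with a 95% exact interval is given. Such intervals and floors cover counting error only. The STAT5B level was also compared by a two-sided exact permutation test over the 6 libraries.

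The text names STAT5B, STAT5A and STAT3, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold. These needed groups that did not overlap, a mean of at least 5 CPM in a group and a gene symbol that was not a clone, LOC, LINC or pseudogene name. From each list up to 3 members with the smallest p were named, and all changed members where a list had at most 5. Other STAT genes and further members named to identify small counts were chosen after their values were seen, as was ENSG00000280295. Some genes that the rule takes are not reported here. The design, the lists, the rule and the alternatives were fixed before the data were examined.

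The 34 gene lists covered STAT5 targets, the JAK-STAT pathway, interferon-stimulated genes, NF-kB targets, S-phase and G2/M genes, p53 targets, apoptosis regulators, cholesterol synthesis, fatty acid synthesis and oxidation, glycolysis, hypoxia targets, nuclear and mitochondrial genes of oxidative phosphorylation, the ATF4 response, endoplasmic reticulum chaperones, heat shock genes, NRF2 targets, immediate early genes, YAP/TEAD targets, extracellular matrix, epithelial, mesenchymal, neuronal, kidney, adrenal, haematopoietic and endothelial markers, cancer/testis genes, protocadherins, HOX genes, ribosomal proteins and histones. Lists with at least 5 tested members were tested with camera (preset correlation 0.01) and with fry from limma 3.58.1. Camera was repeated with a correlation estimated from each list. That version also takes its degrees of freedom from the 6 libraries, so a call can end without correlation between genes. Counts per list are given over all genes and adjusted over the list alone.

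Chromosomal position was examined as the median log2 fold change in blocks of 50 neighbouring tested genes. The range was the 95% range of the most extreme block over 10000 random gene orders.

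Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (1 CPM in 3 libraries), offsets from effective length, limma on log2(TPM + 1), the replicate number as a block, a test against a 1.2-fold change, leaving out each library in turn, and blocks of 25 and 100 genes. Offsets for gene length and GC content per library, fitted with splines of 5 degrees of freedom on genes with a mean log2 CPM of at least 1, were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading the files, the block test and the figures.

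The count tests were tested on simulated data drawn from the means and sizes of these libraries over 15958 genes. For this comparison edgeR recovered 72% of 100 genes changed 1.5-fold and 86% of 100 changed 2-fold, with 17 false calls among 191 (8.90%). With a GC trend planted, edgeR made 4773 calls, and 183 with the offsets, of which 10 were false. A further planted set raised 1.2-fold was counted as true. No length trend was planted, so the simulation does not check the length part of the offsets.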

Results

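RNA sequencing measured mRNA levels in HEK293, a human embryonic kidney cell line transformed with adenovirus DNA, in 3 wild-type and 3 STAT5B knockout libraries. STAT5B is a transcription factor that JAK kinases phosphorylate after cytokine or growth hormone signalling. The knockout cells were made with CRISPR/Cas9, and per the labels clones mutated on both alleles were picked by sequencing and by protein blot. The same protocol text also speaks of GS knockout clones, a name it does not explain, so the genotype rests on the labels. The wild-type libraries held 17686407, 19040818 and 20279181 estimated counts, and the knockout libraries 17613140, 21099813 and 17494958. Between 22363 and 23110 of 60609 genes had a count above 0 in a library. Mitochondrial mRNAs took 1.76%, 1.97% and 1.67% of the counts in the wild type and 1.94%, 2.43% and 1.38% in the knockout. The labels do not state whether the 3 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical. Because the knockout cells were picked clones, other differences between clones and wild-type cells cannot be told apart from loss of STAT5B.

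The comparison of knockout with wild type asked which mRNAs differed between cells labelled as STAT5B knockout and wild-type cells. The targeted gene itself, STAT5B (ENSG00000173757, minus strand of chromosome 17, 42199168 to 42276707, hg38), was still transcribed in every knockout library. Its level was 70.1, 64.6 and 69.4 CPM (counts scaled to 1000000 per library) in the wild type and 63.1, 61.8 and 60.5 CPM in the knockout. The means were 68.0 ± 2.98 and 61.8 ± 1.30 CPM (SD, n = 3 each), a log2 fold change of −0.14 ± 0.047 (SE), with an edgeR adjusted p of 0.0468. A two-sided exact permutation test of these 6 values gave p = 0.1, the smallest that 3 against 3 samples allow. The edgeR call ended in 12 alternative settings, among them DESeq2 (adjusted p = 0.0759) and edgeR without wild-type replicate 1 or 3 (0.160 and 0.148) or knockout replicate 1, 2 or 3 (0.0610, 0.0955 and 0.0938). Counts over a whole gene do not show a small mutation, so they do not check the genotype, and an unnamed gene inside intron 1 on the other strand may share reads with STAT5B.

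Among the related genes STAT2 fell and STAT4 rose. STAT3, an effector of interleukin-6 family cytokines, had 86.0 ± 3.37 CPM in the wild type and 79.0 ± 5.95 CPM in the knockout (edgeR adjusted p = 0.109, and 0.00975 without knockout replicate 3). STAT5A, the close relative encoded beside STAT5B, had 0 counts in each wild-type library and 1 count in each knockout library, which is under the level tested. STAT2, an effector of interferon signalling, fell by 0.26 on the log2 scale (SE 0.061, edgeR adjusted p = 0.0065). STAT4, an interleukin-12 effector expressed at a low level here, rose from 1.26 ± 0.049 to 2.30 ± 0.55 CPM (edgeR adjusted p = 0.0294). STAT6 did not pass the test, with a log2 fold change of −0.052. Within 1 Mb of STAT5B, 3 of 56 other tested genes rose, among them the unnamed gene inside intron 1, and 13 fell. Their median log2 fold change was −0.075, and the block of 50 neighbouring genes that holds STAT5B had a median of −0.0925. The STAT5B value of −0.14 thus lies in a stretch that was lower as a whole, and was not tested apart from it.

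**Figure D1:**
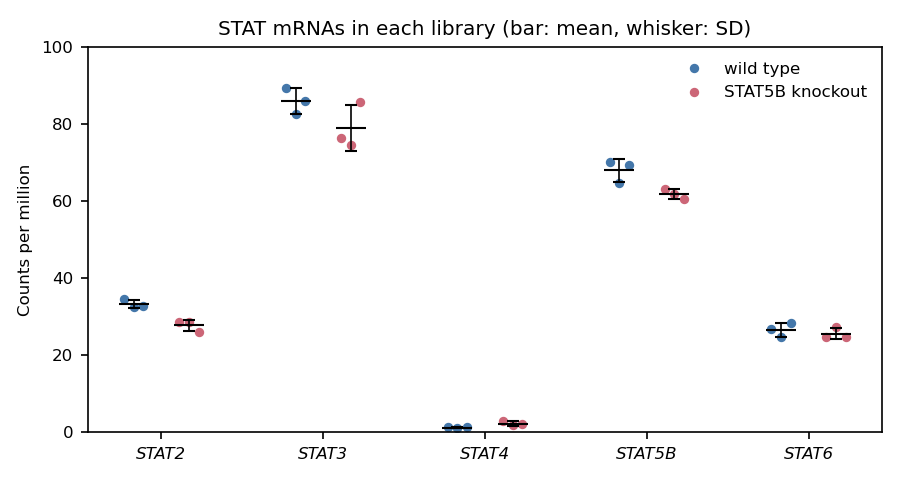
Levels of 5 STAT genes in CPM (vertical axis) in each wild-type and knockout library, with points for single libraries, bars for the mean and whiskers for the SD (n = 3). STAT5B had means of 68.0 and 61.8 CPM, and STAT5A is left out because its counts were 0 or 1 per library.

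Across the transcriptome many genes moved by small amounts. Of 15958 genes tested, 1924 rose and 1818 fell in the knockout at an edgeR adjusted p under 0.05, with a median change of 1.19-fold. Only 140 of these 3742 genes changed more than 2-fold, 57 up and 83 down, and this number was 55 in DESeq2, 293 with no low-count filter, 90 with effective-length offsets and 35 on log2(TPM + 1). Against a 1.2-fold change it was 63. The 3 knockout values lay on one side of the 3 wild-type values for 6163 genes (38.6%, where chance gives 10%). Correlations of log2 CPM across genes were 0.989 to 0.990 within groups and 0.984 to 0.987 between them. Limma on log2(TPM + 1) gave 488 rises and 1135 falls, so 30.1% of its calls were rises against 51.4% in the main test. That scale moved the median of all genes to −0.059. Testing against a 1.2-fold change left 295 genes, and offsets for effective length gave 1734.

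The steepest falls removed some mRNAs almost completely. NLRP1, an inflammasome sensor, had 705 counts over the 3 wild-type libraries and 3 over the 3 knockout libraries, a ratio of 230 (95% counting interval 78.4 to 1119). Its log2 fold change of −7.68 was −8.57 without knockout replicate 1, −7.07 without knockout replicate 2 and −2.72 on log2(TPM + 1). TMEM47, a protein of cell junctions, fell from 6.18 ± 1.39 to 0.197 ± 0.028 CPM (SD, n = 3), a log2 fold change of −4.92 (SE 0.31) with an edgeR adjusted p of 2.23e-07. PRKCB, a protein kinase C isoform, fell from 42.6 ± 2.66 to 9.86 ± 0.68 CPM. NEFM, the medium neurofilament chain of neurons, fell from 438 ± 16.5 to 198 ± 16.9 CPM. FBXL16, an F-box protein, and SMAP1, a GTPase-activating protein for ARF6, fell, with log2 fold changes of −2.68 and −1.98. LRATD2, SLC13A3, a sodium-dependent dicarboxylate carrier, and IFITM2, an interferon-induced membrane protein, also fell (log2 fold changes −1.72, −1.05 and −1.06). HOXA-AS3, an antisense RNA of the HOXA cluster, fell by 1.36 on the log2 scale. Among all of these the highest edgeR adjusted p was 2.08e-04, for SLC13A3.

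The largest rises included CALCB, which encodes a calcitonin gene-related peptide, from 8.43 ± 0.81 to 27.0 ± 0.48 CPM (SD, n = 3). Its log2 fold change was 1.68 (SE 0.083) with an edgeR adjusted p of 2.27e-08. OSTN, a secreted peptide of muscle and bone, rose by 1.54 on the log2 scale. The stress-induced transcription factor ATF3 and the growth arrest gene GADD45A rose by 1.39 and 1.02. NFASC, a cell adhesion molecule of axons, and ESRRG, an orphan nuclear receptor, rose by 1.07 and 1.03. Among these genes the highest edgeR adjusted p was 0.00104, for ATF3, and on log2(TPM + 1) the calls of ATF3 and ESRRG ended (adjusted p = 0.0573 and 0.0567). ATF3, GADD45A, NFASC and ESRRG lie on chromosome 1, where 21 of 31 blocks of neighbouring genes were shifted up.

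Some named genes remain uncertain, in most cases because reads can be shared. RN7SL1 and RN7SL2, near-identical copies of the signal recognition particle RNA, had the largest rises among genes with a symbol that met the naming rule. Reads shared between these copies leave the level of each uncertain, but their joint share rose too. It was 0.0011% to 0.0015% of the counts in the wild type and 0.0328%, 0.0222% and 0.0051% in the knockout. The rise thus varied between knockout libraries, and a difference in library preparation was not tested. RN7SL2 had 7.90, 6.66 and 7.53 CPM in the wild type and 189, 132 and 28.2 CPM in the knockout, and RN7SL1 had mean levels of 6.28 and 85.2 CPM. CFAP298-TCP10L, a readthrough of neighbouring genes that overlaps CFAP298, rose by 1.26 on the log2 scale (edgeR adjusted p = 3.63e-04). IFITM2 has close paralogs, and HOXA-AS3 overlaps genes on the other strand, while use of strand in the counting is not given in the sources used here. On log2(TPM + 1), which compresses low levels by construction, the log2 fold changes of TMEM47 and FBXL16 were −1.89 and −2.05.

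**Figure D2:**
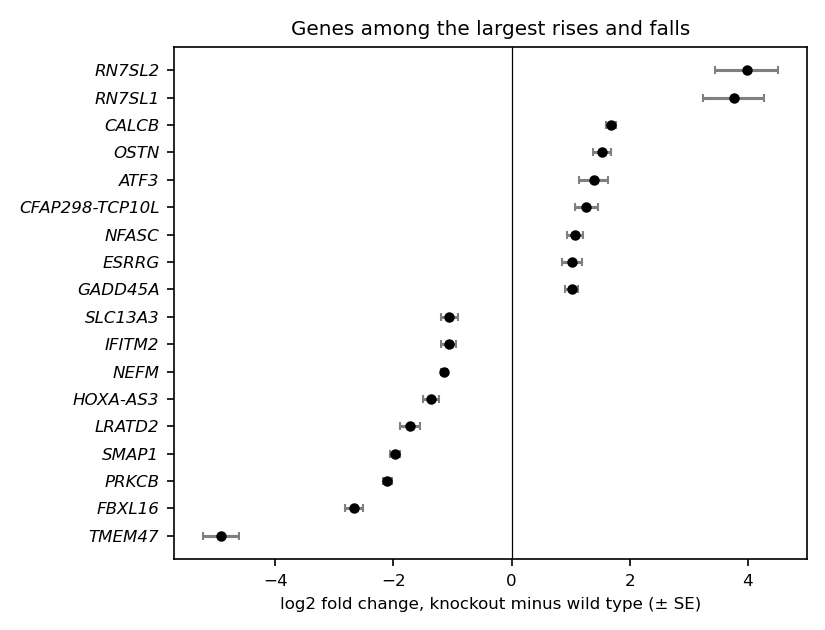
Log2 fold change of knockout against wild type (horizontal axis) for genes among those with the largest rises and falls, with bars of 1 SE from edgeR (3 libraries per group). The values run from −4.92 for TMEM47 to 3.98 for RN7SL2, and NLRP1 is left out because the knockout held 3 counts.

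Genes that STAT5 is known to regulate went both ways. Of 24 tested STAT5 targets, 4 rose (SOCS2, CDKN1A, MCL1 and BCL2L1), 4 fell (CCND1, ID1, SPRED1 and SPRED2) and 16 did not pass. Adjusted over the list alone, 4 rose and 5 fell. SOCS2, a feedback inhibitor of cytokine receptors, rose by 0.59 on the log2 scale and CDKN1A, the cell cycle inhibitor p21, by 0.61, while CCND1, cyclin D1, fell by 0.67. Among 29 components of the JAK-STAT pathway, 6 rose and 7 fell (6 and 8 adjusted over the list alone), and the kinase JAK1 and the ubiquitin ligase CBL fell (log2 fold changes −0.26 and −0.34). Of 28 interferon-stimulated genes, 2 rose, among them B2M, and 5 fell (IFITM2, IFITM3, OAS3, STAT2 and TAP1), with 5 and 5 adjusted over the list alone. No direction passed camera, a test of a list against other genes, for these lists (adjusted p = 0.915, 0.429 and 0.915). The call of B2M ended with length and GC offsets, a setting chosen after seeing the data (log2 fold change 0.014, adjusted p = 0.850), and with effective-length offsets (0.0693), and those of B2M, OAS3 and MCL1 on log2(TPM + 1) (0.205, 0.0611 and 0.238).

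Inflammatory and early response genes were higher in several cases. Of 12 tested NF-kB and inflammatory targets 9 rose and 0 fell, the same counts adjusted over the list alone. No member fell at an unadjusted p under 0.05, and DESeq2 and limma-voom also gave 0 falls, with 6 and 9 rises. The chemokine CXCL8 rose by 2.20 on the log2 scale, the NF-kB inhibitor NFKBIA by 0.48 and the early response gene IER3 by 0.75. CXCL8 was at a low level, with 0.76 ± 0.32 CPM in the wild type and 3.58 ± 1.78 CPM in the knockout (SD over 3 libraries). The list passed camera (adjusted p = 4.74e-04), with an adjusted p = 0.647 with an estimated correlation. Its median score, with genes centred on their mean over the 6 libraries, varied within a group by 0.738 of the group difference. Of 19 immediate early genes, 6 rose, among them JUN by 0.66, and 3 fell (IER2, ETV5 and SPRED1), with 6 and 3 adjusted over the list alone (camera adjusted p = 0.714). On log2(TPM + 1) the log2 fold change of CXCL8 was 1.49.

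Many stress and hypoxia genes rose. Of 32 ATF4 targets and amino acid genes of the integrated stress response, 22 rose and 1 fell (SLC1A5), with 24 and 1 adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, rose by 0.37 on the log2 scale, ATF4 itself by 0.31 and the seryl-tRNA synthetase SARS1 by 0.29. PHGDH and SARS1 lie on chromosome 1, which had a median of 0.15. Of 23 hypoxia targets 16 rose (19 adjusted over the list alone), including VEGFA, an angiogenic factor, by 0.54 and the MYC antagonist MXI1 by 0.45. Their 0 falls were also 0 at an unadjusted p under 0.05, in DESeq2 and in limma-voom, and these 2 tools gave 12 and 16 rises. Of 21 glycolysis genes, 12 rose and 2 fell (SLC2A3 and PFKM), with 13 and 2 adjusted over the list alone, and the pyruvate kinase PKM rose by 0.43 and the enolase ENO2 by 0.77. Of 24 p53 targets, 9 rose and 1 fell (ZMAT3), with 12 and 1 adjusted over the list alone, and SESN2, a stress-induced inhibitor of mTORC1, rose by 0.47. Hypoxia and glycolysis share SLC2A1, LDHA, PGK1, ALDOC and PFKFB4, hypoxia and ATF4 share STC2, and ATF4 and p53 share SESN2. The tests of these lists are thus not independent. Camera gave adjusted p of 1.35e-08 for the ATF4 list, 1.98e-06 for hypoxia, 6.11e-05 for glycolysis and 0.00382 for p53. With an estimated correlation the adjusted p was 0.647, 0.647, 0.647 and 0.342, and with fry 0.0839, 0.122, 0.0884 and 0.00665. Counted away from chromosome 1, a choice made after seeing the data, 16 of 26 ATF4 genes, 14 of 21 hypoxia genes, 10 of 19 glycolysis genes and 5 of 19 p53 targets rose. The p53 call ended with effective-length offsets (adjusted p = 0.0866) and on log2(TPM + 1) (0.0717), as did the call of the glycolytic enzyme GAPDH on log2(TPM + 1) (log2 fold change 0.17, adjusted p = 0.0634).

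Transcripts for translation and respiration were slightly higher, but these list calls ended with offsets for gene length and GC content, a setting chosen after seeing the data. Of 63 cytosolic ribosomal protein genes, 29 rose and 1 fell (RPL23), with 33 and 2 adjusted over the list alone, and RPL27 and RPS7 rose by 0.32 and 0.29 on the log2 scale. Of 42 nuclear genes for oxidative phosphorylation 19 rose (23 adjusted over the list alone), among them the cytochrome oxidase subunit COX7B by 0.48 and the ATP synthase subunit ATP5PB by 0.33. Their falls were 0, with 1 at an unadjusted p under 0.05 and 0 in DESeq2 and in limma-voom, which gave 17 and 18 rises. Of 24 fatty acid oxidation genes, 8 rose and 1 fell (EHHADH), the same counts adjusted over the list alone, and ETFA, an electron carrier, rose by 0.31. Camera gave adjusted p of 4.72e-08, 7.14e-08 and 0.00794 for these lists, each with an adjusted p of 0.342 with an estimated correlation. With those offsets the calls ended (adjusted p = 0.715, 0.210 and 0.0969), and the medians went from 0.089 to −0.018 for ribosomal proteins, from 0.14 to 0.025 for oxidative phosphorylation and from 0.11 to 0.058 for fatty acid oxidation. Away from chromosome 1, 26 of 58 ribosomal, 16 of 38 oxidative phosphorylation and 6 of 22 fatty acid oxidation genes rose. None of the 13 mitochondrially encoded mRNAs passed edgeR, an unadjusted p under 0.05, DESeq2 or limma-voom, with 0 adjusted over the list alone (camera adjusted p = 0.915). Without knockout replicate 2 that list was called lower (adjusted p = 0.00249) and without knockout replicate 3 higher (0.00203), both at the preset correlation. With all libraries its adjusted p was 0.955 with an estimated correlation, which was 0.987 for this list. With no low-count filter MT-ND1, MT-ND5 and MT-ND6 passed edgeR (adjusted p = 2.14e-06, 1.29e-11 and 1.09e-06, log2 fold changes 0.18, −0.25 and −0.30).

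**Figure D3:**
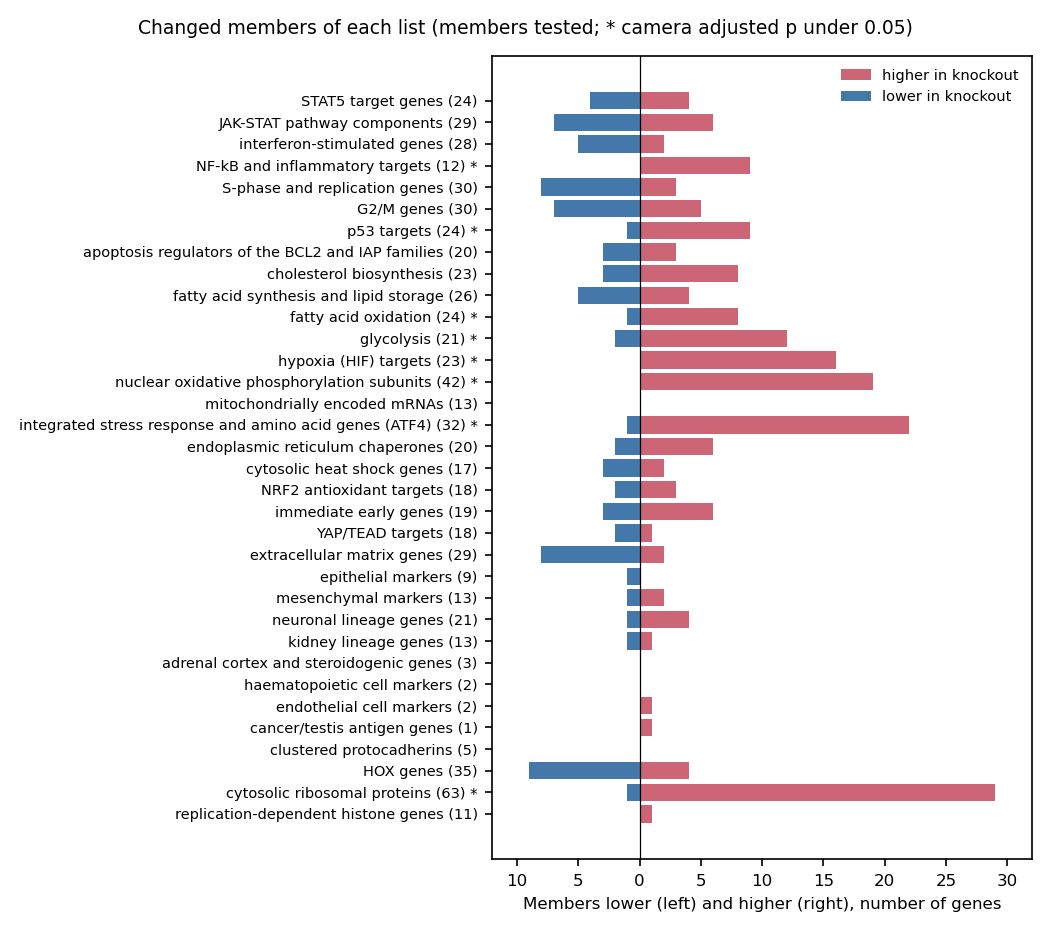
Members of each fixed list that were lower (left) or higher (right) in the knockout at an edgeR adjusted p under 0.05 (horizontal axis, number of genes), with tested members in brackets and a star where camera passed at its preset correlation (8 lists, against 0 with an estimated correlation). The ribosomal list had 29 rises and 1 fall, the ATF4 list 22 and 1, and the hypoxia list 16 and 0, while the ribosomal median was −0.018 with length and GC offsets.

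Cell cycle genes were split. Of 30 S-phase genes 3 rose (PCNA, CDC45 and SLBP) and 8 fell, with 4 and 10 adjusted over the list alone, and PCNA, the sliding clamp of replication, rose by 0.31 on the log2 scale. Of 30 G2/M genes 5 rose (NEK2, CKAP2, HMMR, AURKB and CDC20) and 7 fell, the same counts adjusted over the list alone, and the proliferation marker MKI67 fell by 0.62. Of 20 apoptosis regulators 3 rose (MCL1, BMF and BCL2L1) and 3 fell (HRK, BCL2L11 and XIAP), with 4 and 3 adjusted over the list alone. Of 11 replication-dependent histone genes 1 rose, H4C3 by 0.82, the same count adjusted over the list alone, while the list had a median of −0.16 and 3 members lower at an unadjusted p under 0.05. Of these H3C10 passed as lower in 5 alternatives (adjusted p = 0.0333 to 0.0493), and H2BC12 passed with length and GC offsets (0.00789). The call of H4C3 ended with effective-length offsets (adjusted p = 0.0570), without wild-type replicate 1 (0.0731) or without knockout replicate 1 (0.0674). Camera adjusted p for the 4 lists was 0.577, 0.317, 0.915 and 0.429.

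Lipid and protein folding genes also went both ways. Of 23 cholesterol synthesis genes 8 rose and 3 fell (SC5D, HMGCS1 and SQLE), with 9 and 4 adjusted over the list alone, and the farnesyl diphosphate synthase FDPS rose by 0.31 on the log2 scale. Of 26 genes of fatty acid synthesis and storage 4 rose (FADS1, ELOVL1, LPL and FADS2) and 5 fell (FASN, ACACA, ACSL3, DGAT1 and GPAM), with 6 and 5 adjusted over the list alone. Of 20 endoplasmic reticulum chaperone genes 6 rose, among them the unfolded protein response factor XBP1 by 0.52, and 2 fell (CALR and DNAJB11), with 7 and 2 adjusted over the list alone. Of 17 cytosolic heat shock genes 2 rose (HSPB1 and HSPE1) and 3 fell (HSPH1, HSPA1B and HSPA4), the same counts adjusted over the list alone. Of 18 NRF2 targets 3 rose (PRDX1, GCLM and FTL) and 2 fell (TXNRD1 and TXN), with 4 and 2 adjusted over the list alone. PRDX1 and GCLM, which rose by 0.20 and 0.23, lie on chromosome 1, which had a median of 0.15. Camera adjusted p for the 5 lists was 0.306, 0.915, 0.429, 0.750 and 0.714. HSPA1B has a near-identical copy and is uncertain. With effective-length offsets its call and those of FTL and TXNRD1 ended at similar log2 fold changes (from −0.15 to −0.16, from 0.14 to 0.13 and from −0.14 to −0.15, adjusted p = 0.0585, 0.0690 and 0.189). The call of HSPA4 ended with a log2 fold change that went from −0.10 to −0.0061 (adjusted p = 0.939). On log2(TPM + 1) the calls of HSPE1, PRDX1, GCLM, HSPA4, FTL and TXNRD1 ended (log2 fold changes 0.14, 0.12, 0.14, −0.074, 0.062 and −0.22, adjusted p = 0.0906, 0.125, 0.153, 0.207, 0.376 and 0.0697). With length and GC offsets those of HSPE1 and FTL ended (0.10 and 0.085, adjusted p = 0.0769 and 0.0885). Single libraries also ended the calls of HSPA1B (without wild-type replicate 1 or 2 or knockout replicate 1, adjusted p = 0.0562, 0.0803 and 0.0706), HSPA4 (without wild-type replicate 1, 2 or 3 or knockout replicate 1, 0.0528, 0.0869, 0.0663 and 0.0702) and TXN (without wild-type replicate 2 or knockout replicate 1, 0.0737 and 0.0648).

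Several matrix genes fell. Of 29 extracellular matrix genes 8 fell and 2 rose (NID1 and LOX), with 9 and 2 adjusted over the list alone. SPARC, a collagen-binding matrix protein, had 252 counts over the wild-type libraries and 1 over the knockout libraries, a ratio of 247 (95% counting interval 43.9 to 9787). The size of its fall depended on the setting. The log2 fold change was −9.35 without knockout replicate 2, −6.83 in limma-voom, −6.73 with effective-length offsets and −2.73 on log2(TPM + 1). The camera adjusted p of the matrix list was 0.162, 0.0401 without wild-type replicate 3, and 0.885 with the direction turned to higher with length and GC offsets. Of 35 HOX genes, which pattern the body axis, 9 fell and 4 rose (HOXC4, HOXC11, HOXD13 and HOXB7), with 10 and 4 adjusted over the list alone (camera adjusted p = 0.185), and HOXA13 fell by 0.59 on the log2 scale. Of 18 YAP/TEAD targets 1 rose (DLC1, by 0.45) and 2 fell (AMOTL1 and PTPN14), the same counts adjusted over the list alone (camera adjusted p = 0.915). The log2 fold change of DLC1 was −0.10 with effective-length offsets and −0.14 on log2(TPM + 1), and neither passed, and the call of AMOTL1 ended with length and GC offsets (adjusted p = 0.0777).

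Changes among lineage markers were small in number and are to be read against the 23.4% of all tested genes that changed. Of 9 epithelial markers 1 fell (MAL2, by 1.58 on the log2 scale, and by 0.55 on log2(TPM + 1)), and of 13 mesenchymal markers 2 rose (ACTA2, smooth muscle actin, by 1.06, and VIM by 0.12) and 1 fell (CDH2), both the same adjusted over the list alone. Of 21 neuronal genes 4 rose (ENO2, CNTN1, UCHL1 and SYT1) and 1 fell (NEFM), and of 13 kidney lineage genes 1 rose (EYA1) and 1 fell (SALL1), again the same adjusted over the list alone. Camera adjusted p for these lists was 0.714, 0.762, 0.429 and 0.915. Adjusted over the list alone, SCARB1 was lower among 3 adrenal genes, of which 0 passed over all genes, 1 at an unadjusted p under 0.05 and 0 in DESeq2 and limma-voom. EGFL7 rose among 2 endothelial markers and PRAME as the single tested cancer/testis gene, each also adjusted over the list alone. Among 2 haematopoietic markers (HBA1 and CORO1A) and 5 clustered protocadherins, whose shared sequence makes counts uncertain, 0 passed edgeR, also adjusted over the list alone, at an unadjusted p under 0.05, in DESeq2 and in limma-voom (camera adjusted p of the protocadherins 0.915). With effective-length offsets 6 calls ended. The log2 fold changes of EYA1, SYT1, VIM, EGFL7 and PRAME went from 1.12 to 0.88, from 0.25 to 0.30, from 0.12 to 0.095, from 0.37 to 0.35 and from 0.23 to 0.24 (adjusted p = 0.199, 0.117, 0.107, 0.0776 and 0.0700), and that of SALL1 from −0.21 to −0.017 (adjusted p = 0.922). The same 6 calls ended on log2(TPM + 1) (log2 fold changes 0.47, 0.21, 0.026, 0.28, 0.17 and −0.079, adjusted p = 0.249, 0.294, 0.683, 0.0896, 0.184 and 0.622). That of SYT1 ended in DESeq2 (0.24, adjusted p = 0.0731), and those of VIM and SALL1 with length and GC offsets (0.067 and −0.17, adjusted p = 0.157 and 0.0640). Without wild-type replicate 2 those of SALL1, VIM, EGFL7 and PRAME ended (0.0733, 0.0752, 0.0547 and 0.0631), without wild-type replicate 1 those of SALL1, SYT1 and VIM (0.112, 0.0947 and 0.0671), and without knockout replicate 1 or 2 those of SALL1 (0.108 and 0.0597) and SYT1 (0.0671 and 0.0508). SCARB1 passed without knockout replicate 3 (0.0104), and the protocadherin PCDHGC4 without knockout replicate 2 (0.0158).

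Of 30 lists large enough for camera, 8 passed with its preset correlation of 0.01 and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05. Fatty acid oxidation lost its call at an estimated correlation of −0.028, below the preset value. Correlation between genes thus does not account for every lost call. The test named fry called 4 of the 8 in one direction (p53, fatty acid oxidation, oxidative phosphorylation and ribosomal proteins), and not ATF4, hypoxia, glycolysis or NF-kB targets (adjusted p = 0.0839, 0.122, 0.0884 and 0.0839). For 9 lists, each with a camera adjusted p of at least 0.429, the median, the mean and the camera direction differed in sign: STAT5 targets, JAK-STAT, interferon-stimulated, S-phase, apoptosis, fatty acid synthesis, mitochondrially encoded, YAP/TEAD and kidney genes.

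Genes on chromosome 1 were higher as a group. Their median log2 fold change was 0.15 over 1574 tested genes, or 1.11-fold, while random gene sets of this size gave −0.004 to 0.018. Of the 22 other chromosomes examined, 5 lay above and 9 below the random range for their own size, with medians between −0.066 and 0.051. On this chromosome 564 genes rose and 76 fell, so 35.8% rose against 9.50% of the 14269 genes elsewhere. In blocks of 50 neighbouring genes, 21 of 31 blocks of chromosome 1 lay above the range of random gene orders (−0.12 to 0.15). They spanned 32680360 to 244845057 and had medians of 0.15 to 0.30, and 25 of the 31 had a median above 0. The first 6 blocks, up to 28096422, had medians of −0.087 to −0.045. On chromosome 17, 189 of 944 genes fell, and 5 of 18 blocks lay below the range and 1 above. Its blocks up to 19062669 all had medians above 0 (0.080 to 0.17). Its later blocks, among them that of STAT5B, all had medians below 0 (−0.19 to −0.059). Of 303 blocks in the genome, 32 lay outside the range, the others being 3 on chromosome 15 and 1 each on X and 11. On chromosome 15 the blocks from 60419609 on all had medians above 0 (0.071 to 0.18). Genes are not independent replicates, so these ranges describe gene order and not the spread between cultures. With blocks of 25 genes, 18 of 622 lay outside, and with blocks of 100 genes 25 of 147 (16 above and 9 below). Other genes named above that rose and lie on chromosome 1 are MCL1, JUN, SESN2, ATP5PB, NEK2, CDC20, FDPS, ELOVL1 and NID1.

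**Figure D4:**
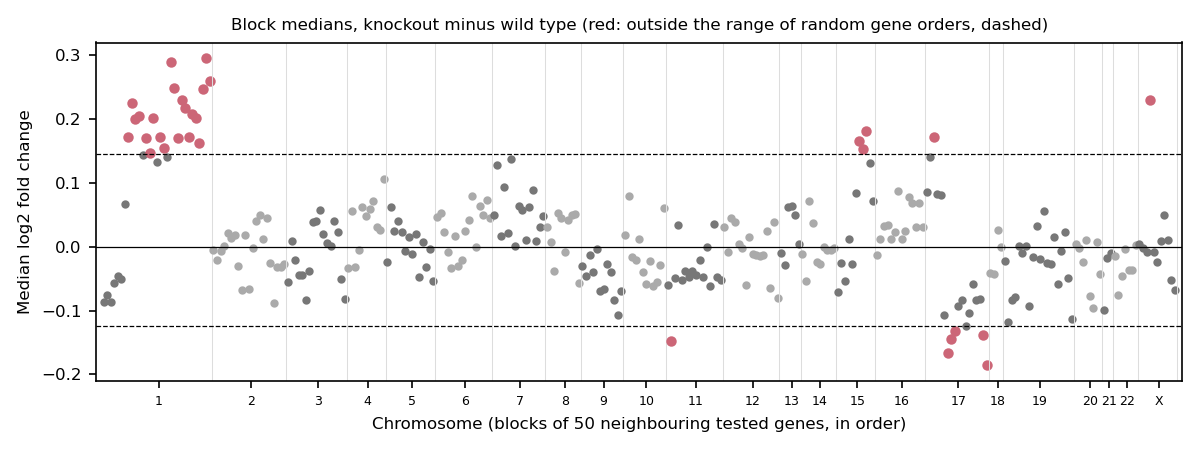
Median log2 fold change of knockout against wild type (vertical axis) in blocks of 50 neighbouring tested genes along the chromosomes (horizontal axis, genome order), with dashed lines at the range of random gene orders, −0.12 to 0.15. Blocks outside the range numbered 32, of which 21 lay on chromosome 1.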

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

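In this part the length and GC offsets are the tests chosen only after the result was seen. RLE scaling, DESeq2, limma-voom, the stricter filter, no filter and the replicate block gave 3740, 3038, 3645, 3806, 4081 and 3660 changed genes, of which 3657, 2995, 3594, 3702, 3564 and 3504 were shared with the 3742, and no shared gene had the opposite sign. DESeq2 gave no adjusted p for 2166 genes. Effective-length offsets gave 1734 changed genes (891 higher, 843 lower), of which 1630 (43.6% of the 3742) were shared. On log2(TPM + 1) there were 1623 (488 and 1135), of which 1379 (36.9% of the 3742) were shared. The test against a 1.2-fold change, which asks for more by construction, gave 295 (155 and 140). Length and GC offsets gave 3282 changed genes, 2712 of them shared. Leaving out single libraries gave 2618 to 3575 changed genes (1339 to 1789 higher, 1279 to 1786 lower), and 122 to 166 changed more than 2-fold. Genes changed more than 2-fold numbered 55 in DESeq2, 293 with no filter, 90 with effective-length offsets, 35 on log2(TPM + 1) and 63 against a 1.2-fold change. Where the construction does not show it, the cause was not tested.

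The STAT5B log2 fold change of −0.14 stayed negative but lost its call in DESeq2 (−0.14, adjusted p = 0.0759), with no filter (−0.14, 0.0620), effective-length offsets (−0.24, 0.104), log2(TPM + 1) (−0.30, 0.0844), against a 1.2-fold change (−0.14, 1) and with length and GC offsets (−0.10, 0.115). Without single libraries it lay between −0.17 and −0.12 and kept its call only without wild-type replicate 2 (adjusted p = 0.0325). With the replicate block STAT5B had −0.14 (adjusted p = 0.0554), and MT-ND5 and MT-ND6 passed as lower (−0.29 and −0.36, adjusted p = 0.0130 and 0.0424). Same-numbered libraries had deviation correlations of 0.004, 0.104 and 0.042, against −0.098 to 0.052 for differently numbered libraries. In both groups replicate 2 had the highest mitochondrial share and replicate 3 the lowest. Whether the numbers pair the samples stays open, and the labels do not say. Among the list calls 8 became 5 with length and GC offsets, 0 with an estimated correlation and 8 to 9 without single libraries. Blocks of 25 genes gave 18 outside the random range and blocks of 100 genes 25.

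With length and GC offsets the camera direction turned for 9 lists, of which the ribosomal list was the 1 called before. Signs turned for the ribosomal list (−0.018 with length and GC offsets), CYB5A (−0.036 with those offsets) and DLC1 (−0.10 with effective-length offsets, −0.14 on log2(TPM + 1)). Without single libraries MT-ND1 ranged from −0.055 (knockout replicate 2 left out) to 0.39, FDX1 from −0.099 to 0.038 (knockout replicate 3), HBA1 from −0.25 to 0.12 (above 0 without wild-type replicate 3 or knockout replicate 1) and CORO1A from −0.13 to 0.051 (above 0 without wild-type replicate 2 or 3 or knockout replicate 1 or 3). Of 102 changed named genes, 38 kept their call in every alternative and 64 lost it in at least 1, 25 of them outside the 1.2-fold and single-library settings. The depth limits low genes such as STAT5A, with at most 1 count per library.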

Other observations

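In this part the tests with effective-length offsets for fragment length, with length and GC offsets and of a copy number difference of chromosome 1, and the choice of ENSG00000280295, were made only after the result was seen. ENSG00000280295, an unnamed gene on the plus strand of chromosome 17 (42233832 to 42235469), lies inside intron 1 of STAT5B, 1694 bases from exon 2. It had 0 counts in the 3 wild-type libraries and 28, 27 and 34 in the knockout libraries, at least 30.3-fold higher against 3 counts over the group (edgeR adjusted p = 2.75e-05). Use of strand in the counting is not given in the sources used here, so these reads cannot be assigned to this gene rather than to STAT5B transcripts. RN7SL1 and RN7SL2 together took 0.0015%, 0.0011% and 0.0015% of the counts in the wild type and 0.0328%, 0.0222% and 0.0051% in the knockout.

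The number of changed genes was 3742 in the real split of the 6 libraries and at most 1 in the other splits, and the real split was the 1 split of 10 with as many. With 10 splits a share under 0.05 cannot be reached. Each other split puts knockout and wild-type libraries on both sides, so a group difference of any cause keeps its count low. The contrast therefore says nothing on the cause. Length and GC offsets gave 3282 changed genes, 2712 of them shared with the 3742, so a trend with length or GC was not the whole of the difference.

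Short mRNAs for ribosomal proteins and oxidative phosphorylation were higher in the knockout, with a median log2 fold change of 0.097 (bootstrap interval over genes 0.066 to 0.14, which leaves out correlation between genes), but with an estimated correlation neither list was called (adjusted p = 0.342). With length and GC offsets this median was −0.001 (interval −0.022 to 0.031), and the calls ended as the medians moved to near 0, with length and GC not tested apart. In 5 groups of genes by length, the shortest (median 925 bases) had 509 rises and 82 falls and the longest (median 5363 bases) 231 and 896. At camera's preset correlation, leaving out single libraries kept both calls (highest adjusted p = 1.16e-06), which argues against 1 library as the cause of these calls. Effective-length offsets kept both calls too (higher camera adjusted p = 1.37e-05). This argues against mean fragment length alone as the cause, and these offsets do not test a bias with gene length. A length or GC bias between libraries may account for the shift, and a real change shared by short mRNAs would be removed by the same offsets and stays open, as does the genotype.

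Hypoxia, glycolysis, ATF4 and p53 genes were higher in the knockout, with a median log2 fold change of 0.23 (interval over genes 0.18 to 0.28, which leaves out correlation between genes), but with an estimated correlation (0.698, 0.507, 0.568 and 0.028) no list was called (adjusted p = 0.647, 0.647, 0.647 and 0.342). With length and GC offsets the median was 0.22 (interval 0.16 to 0.25), which argues against length or GC bias. The mean score of these lists, with each gene centred on its mean over the 6 libraries, was −0.11, −0.19 and −0.044 in the wild type and 0.15, 0.057 and 0.16 in the knockout. The largest range within a group was 0.619 of the group difference, and replicate 2 scored lowest in both groups. The culture state of single flasks, or a state shared by libraries of the same number, may contribute. These were not tested apart, and the labels do not say whether the libraries came from separate flasks. Loss of STAT5B stays open and was not tested apart from culture or from other differences between the picked clones and the wild-type cells.

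Neighbouring genes moved together in 32 blocks, and in 29 of these with length and GC offsets too, which argues against chance order of genes and against length or GC bias. As a whole, chromosome 1 lay above the other genes by at least 0.12 on the log2 scale in each of 5 groups of genes by expression level. For single libraries each gene was first centred on its mean over the 6 libraries. The chromosome 1 median relative to other genes was then −0.081, −0.063 and −0.077 in the wild-type libraries and 0.079, 0.070 and 0.076 in the knockout libraries. The centring makes the groups mirror each other around 0, so only the difference between them has meaning. These values describe the shift again, and any cause acting on the whole chromosome would give them, so they do not single out copy number. A candidate explanation is a copy number difference of most of chromosome 1 between the cells compared, leaving out its first 6 blocks, whose medians were −0.087 to −0.045. Parts of chromosomes 15 and 17 were shifted too and were not examined in this way. No DNA data were analysed here, and an effect of STAT5B loss on any of these genes stays open and untested.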
